A study of Mus musculus with 2 samples.

How the data were processed

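Spatial gene expression was measured in sections of 2 whole mouse embryos at E12.5. Per the labels' protocols, fresh tissue was frozen and embedded, sections of 10 µm were stained with haematoxylin and eosin and scanned, and libraries were made with a Visium HD kit. The deposited matrices hold UMI counts per gene and 16 µm bin, which the authors made with Space Ranger 3.1.1 against the build mm10, per the submitters' processing notes. The file headers name the same software, and the values are whole numbers with different totals per embryo, with no normalization. Filters and other settings of that step are not given in the sources used here. The authors' deposited clusters, 33 for replicate 1 and 29 for replicate 2, were used only as an alternative grouping of bins. Gene symbols were taken from the deposited feature lists of 19059 genes. Of 538 genes on the lists used here 533 were measured, and Ccnb1, Cx3cr1, Eno1 and Xist were not. Aldoa was left out as well, since it is 1 of 6 symbols that occur more than once. No coordinates are given, since none were needed.

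The file meant to list the bins of replicate 1 holds a copy of its gene list. The bin order of this embryo was therefore taken from its deposited cluster file, which lists as many bins, 85017, as the matrix has columns. In replicate 2, whose bin list is intact, the cluster file has the order of the bin list apart from 12 bins with 0 UMIs. The order was checked by correlating each of 4 genes between touching bins. The correlations in replicates 1 and 2 were 0.816 and 0.826 for Alb, 0.821 and 0.825 for Col2a1, 0.667 and 0.757 for Myh7, and 0.467 and 0.464 for Tubb3. After shuffling the bins they lay between -0.003 and 0.007.

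Bins with at least 100 UMIs were kept, 84072 in replicate 1 and 92228 in replicate 2, which left out 945 and 1020 bins. The tissue covered 21.8 and 23.9 mm². Totals of 97094225 and 128089609 UMIs mean that a count of 3 in a whole library, the floor used for genes at 0, corresponds to 0.0309 CPM in replicate 1. The embryo is the replicate throughout. Both embryos come from separate biological samples, per the series' design text, and each gives every region, so the embryo entered each model as a block. With n = 2, p-values rest on a spread that is pooled over genes, and over regions where several are compared.

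Regions came from a joint clustering of both embryos. It used 2000 variable genes, log counts per 10000 scaled within each embryo, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1. Every gene on the compared lists, 377 in all, was left out of the clustering. Regions with fewer than 200 bins in an embryo were not compared. Regions are called by leading genes with at least 50 CPM, and no cell type makeup was estimated. The adjusted Rand index with the authors' clusters was 0.395 in replicate 1 and 0.296 in replicate 2. UMIs were summed per region and embryo and tested with edgeR's quasi-likelihood test, each region against the mean of the others, with Benjamini-Hochberg adjustment over all genes and regions, and a call needed an adjusted p under 0.05 and a 2-fold difference. The fit had 30 residual degrees of freedom. Log2 folds per embryo use log2 of CPM plus 0.5. They are printed in place of the fitted folds for single genes in regions, because a fitted fold depends on the prior count where a gene is at 0 in other regions.

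For ligands and receptors, 112 known pairs were listed and 111 had both genes measured. The 101 pairs whose genes each had at least 300 UMIs in each embryo were tested. For each pair and embryo, the products of ligand and receptor UMIs over all bins more than 0 and at most 3 bins apart were divided by the value expected from the bin totals. The median over pairs was set against 10000 random re-pairings within the list (two-sided permutation test). Single pairs were tested against 0 with limma on the log2 ratios of both embryos, adjusted over the 101 pairs.

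For 7 sources of signals, a source bin is the centre of a 3 by 3 block with at least 3 UMIs of the source. Bins at most 3 bins (48 µm) from a source bin, source bins left out, were compared with bins at least 12 bins (192 µm) from any. The same number of bins was drawn from each region of each embryo. Near bins numbered 1692 and 1287 for Shh in replicates 1 and 2, 7327 and 8048 for Bmp4, 1091 and 517 for Fgf8, 4279 and 4720 for the Wnt ligands, 4637 and 3621 for Dll1, 8123 and 7675 for Aldh1a2, and 1684 and 3083 for Vegfa. UMI sums were tested with edgeR with the embryo as a block, adjusted over all genes tested for that source. The median log2 fold of each of the target lists, which hold 59 genes together, was ranked among 10000 random lists matched on mean expression.

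Libraries of the 2 embryos were compared by their CPM without a test, and the ratios of named genes have 95% counting intervals.

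Lists, tests, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The alternatives chosen after seeing the data match bins on region and on 10 classes of bin depth, or leave out bins that touch a source bin. For regions, the rule names the 3 genes of each list with the largest fold in any region, among those past the threshold and higher in both embryos, and every globin. For pairs it names the 10 highest and 5 lowest past the threshold and the highest of each family. For sources it names every target past the threshold, the 2 most abundant others of each list, and the 5 genes outside the list with the largest log2 fold and at least 200 UMIs per embryo. Between embryos it names Xist, the Y-linked genes and the 10 largest ratios in each direction.

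Each procedure was tested on simulated data. For regions, edgeR recovered 94% of genes simulated with a 2-fold rise and 80% with a fall to 0.5-fold, and all of those simulated at 4-fold and 0.25-fold, with 1 false call among 13696 genes. Near Shh, it recovered 36% of simulated 1.5-fold rises, 14% of falls to 0.667-fold, and all 3-fold rises and falls to 0.333-fold, with 8 false calls among 12244 genes. Near Aldh1a2 it recovered 82% of 1.5-fold rises and 66% of falls to 0.667-fold, with 9 false calls among 13912 genes. The co-occurrence statistic had a largest error of 0.21 on the log2 scale for sparse simulated genes and 0.06 for dense ones, the dense case having been added after the sparse one was seen. With limma, all 40 pairs simulated at a log2 ratio of 1 were recovered with 1 false call among 60. The simulated spread between embryos was smaller than that of most pairs named below, so recovery in the data is likely lower.

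Alternatives covered DESeq2 with its size factors, no filter on low counts, 500 UMIs per bin, resolutions 0.5 and 2, no block, no fold threshold, other distances, source definitions and matchings, expected values within regions or within the authors' clusters, 2000 UMIs per gene, and each embryo left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. The tissue images, their scale factors and the adjacent sections were not used here. Results that need certain genes, single pairs among them, are not reported here in the text or the plots, while counts over whole lists include every gene tested.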

Results

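Whole mouse embryos at E12.5, the stage of gestation at which limbs, face, heart chambers and most ganglia have formed and the liver is the main site of blood formation, were profiled with Visium HD. In this assay, transcripts of a tissue section are tagged with a barcode that gives their position on a slide. A fresh-frozen 10 µm section was used from each of 2 embryos, which came from separate biological samples and form a single group. The values are counts of unique molecular identifiers (UMIs) per gene in square bins with sides of 16 µm. A bin may hold several cells or part of a cell. Replicate 1 had 85017 bins and 97094225 UMIs, with a median of 998 UMIs and 836 detected genes per bin. Replicate 2 had 93248 bins and 128089609 UMIs, with medians of 1172 UMIs and 977 genes. The study is about locating ligand-receptor signalling in such sections. With a single group there is no treated or control arm, and the comparisons were made between places within the same embryos, with the embryo as the replicate (n = 2).

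Bins from both embryos fell into 36 regions, and the 31 with at least 200 bins in each embryo were compared. Muscle, liver, cartilage, skin, heart, brain and ganglion genes led different regions. Region 2, led by the muscle genes Myh3, Myog and Acta1, held 11.9% of the bins of replicate 1 and 3.75% of those of replicate 2. Region 4, led by the liver genes Alb and Afp together with the blood gene Hemgn, held 10.9% and 2.94%. Region 22, also led by Alb and Afp, held 265 bins in replicate 1 and 3069 bins in replicate 2. Region 1 was led by Pax1, Meox1 and Matn4 (8.71% and 9.03%), region 10 by the cartilage genes Matn1, Acan and Cnmd, and region 12 by the epidermal keratins Krt5 and Krt14. The heart genes Myl2 and Myl3 led region 16, and Myl7 and Myh6 led region 24. Among neural regions, Lamp5, Skor1 and Rab3c led region 7, Prph, Ppp1r1c and Sncg led region 8, Fezf1, Celf3 and Islr2 led region 14, and Nr2e1, Sox1 and Neurog2 led region 15. These genes took part in forming the regions and serve only to call them. Genes on the lists compared between regions did not take part, while other genes named below near sources or between embryos could have. The shares describe 2 single sections, and no difference in them was tested.

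Adult globin genes and genes of haem synthesis, the pathway that makes the oxygen-binding group of haemoglobin, were higher in the regions led by Alb and Afp. All 8 haem synthesis genes were higher in regions 4, 22 and 32 than in the mean of the other regions, with median log2 folds of 4.02, 4.27 and 3.70. Alas2, which makes the committed step in red cell precursors, stood at 1359 ± 55.1 CPM (UMIs scaled to the summed UMIs; SD, n = 2) in region 22 (log2 folds 7.68 and 8.32 in replicates 1 and 2, edgeR adjusted p = 1.5e-34). Cpox reached 1549 ± 193 CPM there. The 4 adult globins passed the test in the same 3 regions and in region 6, led by Upk3b, Alb and Afp. In region 22, Hba-a2 stood at 59712 ± 5011 CPM, Hbb-bs at 21540 ± 5080 CPM, Hbb-bt at 6797 ± 1073 CPM and Hba-a1 at 323 ± 23.2 CPM. Hba-a1 and Hba-a2, like Hbb-bs and Hbb-bt, are near-identical copies, so the split of UMIs within each of these is uncertain.

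The 3 embryonic globins, which are made by the early red cells that circulate from the yolk sac, all passed the test in regions 4, 6, 22 and 32 and in region 5, led by Slc22a6, Ranbp3l and Cldn11. Hbb-bh1 was highest in region 22 in both embryos, at 590 ± 41.8 CPM (log2 folds 7.08 and 7.43). In region 4, Hbb-y and Hba-x stood at 110 ± 52.0 and 59.5 ± 13.8 CPM, but in replicate 1 Hbb-y was higher in region 5 (102 against 72.9 CPM) and Hba-x in region 22 (60.6 against 49.7 CPM). In region 5, Hbb-y stood at 85.7 ± 22.6 CPM (log2 folds 2.27 and 1.99, edgeR adjusted p = 1.9e-07) and Hba-x at 26.6 ± 2.31 CPM. Hbb-bh1 also passed there, at 9.47 ± 8.06 CPM, with log2 folds of -0.19 and 1.95 in replicates 1 and 2. Of the adult globins, Hba-a1 passed in region 5 (3.32 ± 0.262 CPM, log2 folds of only 0.34 and 0.94 in replicates 1 and 2) and Hbb-bs did not (93.5 ± 43.4 CPM, edgeR adjusted p = 0.0942). In region 16, led by heart genes, Hba-x stood at 25.5 ± 16.8 CPM, Hbb-y at 62.3 ± 21.2 CPM, Hba-a2 at 592 ± 198 CPM and Hbb-bs at 166 ± 29.7 CPM, and all of these passed the test. In region 24, also led by heart genes, Hba-a2, Hbb-bs and Hbb-bt passed, with log2 folds of 2.02, 2.25 and 2.36 in replicate 1 but 0.34, 0.68 and 0.55 in replicate 2.

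Cell division genes were higher in regions 4, 22 and 32, led by Alb and Afp, and lower in several regions led by neural genes. In region 6, led by Upk3b, Alb and Afp, DESeq2 called 0 of 19 higher, with a median log2 fold of 0.34. Of 19 tested cell cycle genes, 18 were higher in region 4, 18 in region 22 and 13 in region 32, with median log2 folds of 1.53, 1.52 and 1.21. Mki67, a marker of dividing cells, stood at 2123 ± 465 CPM in region 22, and Rrm2, which makes the building blocks of DNA, at 2132 ± 405 CPM. Cdc6, which licenses replication origins, showed log2 folds of 2.84 and 2.88 there. In region 15, led by Nr2e1 and Sox1, 6 cell cycle genes were higher. All 19 were lower in each of the regions 7, 8 and 14, with median log2 folds of -3.54, -1.87 and -2.15.

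Metabolic genes also differed between regions. Of 13 cholesterol synthesis genes, 11 were higher in region 8, which was led by the peripheral neuron gene Prph, with a median log2 fold of 1.25 (1.29 and 1.18 in replicates 1 and 2). Hmgcs1 stood there at 323 ± 40.1 CPM, Fdps at 271 ± 81.6 CPM and Lss at 71.1 ± 13.8 CPM. Of 10 glycolysis and hypoxia genes, 6 were higher in region 16, led by Myl2 and Myl3, with a median log2 fold of 1.41, and 5 were lower in region 7. Egln3, a gene that low oxygen induces, was highest in region 25, led by the smooth muscle genes Myh11 and Actg2 (194 ± 43.1 CPM). Among glucose transporters, Slc2a3 was highest in region 32, led by Alb and the platelet gene Ppbp (349 ± 52.9 CPM), and Slc2a1 stood at 591 ± 43.8 CPM in region 22.

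Patterning factors differed between regions. Of the 20 brain factors 14 were higher in region 15, and of the 16 limb and face factors 14 were higher in region 13 and 14 in region 23. Each factor of both lists was higher in at least 1 region. Otx2, needed for forebrain and midbrain, stood at 764 ± 265 CPM in region 34, led by the choroid plexus gene Ttr (log2 folds 8.15 and 9.53, edgeR adjusted p = 5.7e-20). Six3, a forebrain factor, stood at 167 ± 34.1 CPM in region 14. Nkx2-1, known from ventral forebrain, lung and thyroid, was higher in region 26, led by the epithelial genes Cldn6 and Cdx2, and differed there between embryos (612 and 198 CPM). In replicate 1 its level was greater still in region 15 (1150 CPM). The face factor Lhx8 stood at 364 ± 33.6 CPM in region 20, led by Cxcl14 and Tnn. Tbx5, a factor of forelimb and heart, stood at 280 ± 28.4 CPM in region 24. Alx1, a factor of the face, was higher in region 13, led by the bone genes Ibsp and Sp7, with 831 CPM in replicate 1 and 122 CPM in replicate 2.

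All 37 tested Hox genes, which set position along the body axis, were higher in at least 1 region. In region 1 all 37 passed with edgeR and 32 with DESeq2. Hoxc12, Hoxd13 and Hoxa13 had only 1, 7 and 15 UMIs in replicate 2 as a whole, so folds of these genes rest on replicate 1. The largest folds were those of Hoxb8 in region 7, Hoxd11 in region 9, led by Tcf21 and Wt1, and Hoxc13 in region 12, led by Krt5 and Krt14. Hoxd11, which acts in kidney and limb, stood at 107 ± 73.3 CPM in region 9 (log2 folds 4.66 and 5.75, edgeR adjusted p = 2.3e-15). Hoxc13, which acts in hair and nail, stood at 24.4 ± 21.1 CPM in region 12. Hoxb8 in region 7 rested mainly on replicate 2, with 490 CPM against 5.31 CPM in replicate 1.

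All 14 synapse and neurotransmitter genes were higher in at least 1 region, 13 of them in region 7. The glycine transporter Slc6a5 stood there at 109 ± 46.3 CPM (log2 folds 7.64 and 6.92, edgeR adjusted p = 1.58e-13), but did not pass with DESeq2 (adjusted p = 0.388). The genes for the enzymes that make the inhibitory transmitter GABA, Gad2 and Gad1, were highest in region 14, at 381 ± 180 and 152 ± 48.6 CPM. Of the signalling genes, all 89 tested ligands, 84 of 88 receptors and 57 of 59 signalling targets were higher in at least 1 region. Region 12 had the most ligands (44), and region 3, led by Ccl21a, Col6a6 and Gsc, had the most receptors (39).

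Over all lists together, 367 of 375 tested genes were higher in at least 1 region (edgeR quasi-likelihood test with the embryo as a block, adjusted p under 0.05 and at least 2-fold, 14687 genes tested). For each list, the count of genes higher in a region was the same when adjusted over the list alone. DESeq2 gave 362, and 29 of the 30 genes named by the rule passed with it, Slc6a5 being the exception. Of 149 list medians by region that were at least 2-fold in size, 0 had the other sign with DESeq2. Its scaling moved the median over all genes of a region by at most 0.10 on the log2 scale, in region 34, where Otx2 was highest. The comparison is with the mean of the log values of the other regions, so a gene missing from most regions can pass the test in several. The share that passes among all 14687 tested genes is not given here. The counts therefore do not set the listed genes, ligands and receptors among them, apart from other genes.

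The next question was whether known signalling partners lie close together in the embryo. Known pairs of ligand and receptor were found within 3 bins (48 µm) of each other more often than ligands and receptors paired at random from the same list. The median log2 ratio of observed to expected co-occurrence over 101 pairs exceeded that of re-paired lists by 0.17 (0.17 in replicate 1 and 0.18 in replicate 2). The permutation p was 0.0002, the smallest that 10000 re-pairings can give. The median of the known pairs themselves was 0.20 in replicate 1 but 0.01 in replicate 2, close to the value expected from the bin totals. Re-paired lists lay at 0.03 and -0.17 in replicates 1 and 2. When the expected value was taken within each region, the excess was 0.01 (permutation p = 0.36). Over the 62 pairs whose genes had at least 2000 UMIs it was 0.08 (permutation p = 0.0294), with 0.05 in replicate 1 (permutation p = 0.31) and 0.11 in replicate 2 (permutation p = 0.0078). The log2 ratios of the 101 pairs correlated between the embryos across pairs (Pearson's r = 0.806, Spearman's rho = 0.784), and 81 had the same sign in both. Pairs are not independent replicates.

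Single pairs stood out in both directions, with 8 above and 7 below expectation. The neural adhesion pair Cntn2-L1cam lay together most often, with a log2 ratio of 2.88 ± 0.42 (SD, n = 2, limma adjusted p = 0.0114). Hedgehog ligands lay close to their receptor Ptch1, which is itself a target gene of the pathway. Ihh-Ptch1 had a log2 ratio of 1.51 ± 0.08 and Shh-Ptch1 of 1.38 ± 0.12 (limma adjusted p = 0.0153 and 0.0164). The Notch pair Dll1-Notch1 stood at 1.28 ± 0.21, and Gdnf-Gfra1, which guides enteric and kidney growth, at 1.10 ± 0.36.

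Among the pairs that lay apart, the hedgehog co-receptors Gas1, Boc and Cdon all lay apart from Shh, at -2.44 ± 0.70, -2.21 ± 0.24 and -1.39 ± 0.32 (limma adjusted p = 0.0169, 0.0114 and 0.0217). Fgf15-Fgfr4 stood at -2.05 ± 0.44. Fgf18-Fgfr3 (-1.32 ± 0.41) and Ntn1-Unc5c (-0.90 ± 0.06) also passed and were named after their values were seen. At an unadjusted p under 0.05, limma gave 17 pairs above and 14 below expectation. With the expected value taken within regions, no pair passed limma's threshold (11 above and 15 below at an unadjusted p under 0.05, and no other tool was run). Within regions Cntn2-L1cam had log2 ratios of 0.03 and 0.07 in replicates 1 and 2, whereas Shh-Gas1 had -2.38 and -1.17, and Shh-Ptch1 had 0.60 and 0.39.

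**Figure D1:**
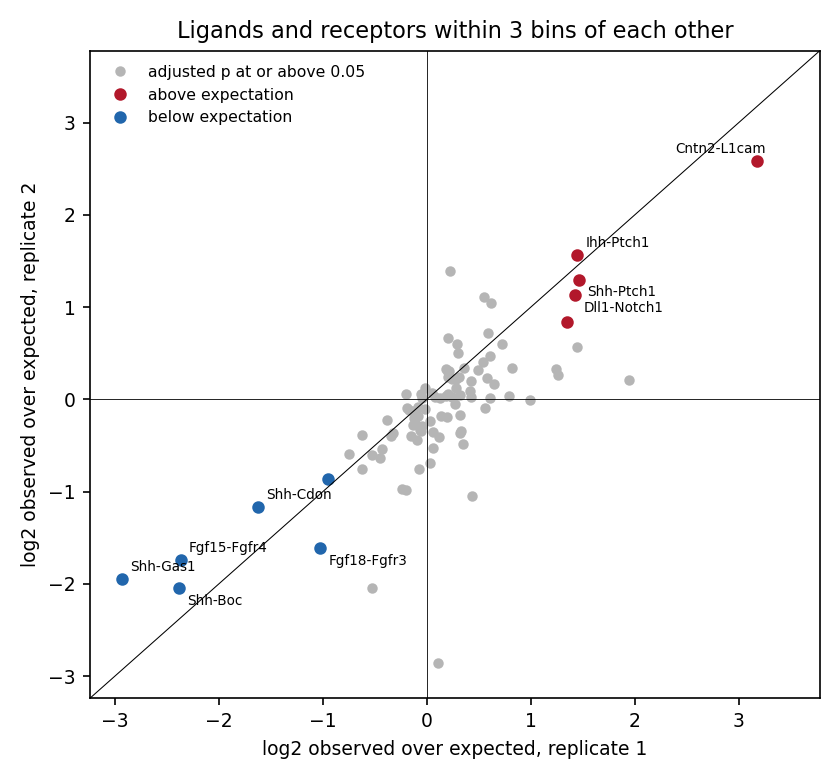
Log2 ratio of observed to expected co-occurrence of ligand and receptor within 3 bins, with replicate 1 on the horizontal axis and replicate 2 on the vertical axis, each point a pair, coloured by limma's adjusted p, and with a line where both embryos are equal. Cntn2-L1cam has the highest mean (2.88), and Shh with Gas1, Boc and Cdon lies far below 0 in both embryos (means of -2.44, -2.21 and -1.39).

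In the remaining families the highest pair did not pass limma's threshold. These were Rspo2-Lgr5 for Wnt (1.01 ± 0.62), Slit1-Robo2 for guidance (0.83 ± 0.39), Gdf5-Bmpr1b for bone morphogenetic proteins (0.81 ± 0.83), Apln-Aplnr for vessels (0.58 ± 0.34) and Ptn-Ptprz1 for other growth factors (0.43 ± 0.33). Efnb3-Ephb1 stood at 0.35 ± 0.01, Pdgfc-Pdgfra at 0.26 ± 0.07 and Tgfb3-Tgfbr2 at 0.25 ± 0.07. Fgf10-Fgfr2 (-0.07 ± 0.59), Cxcl12-Ackr3 (-0.13 ± 0.07) and Edn3-Ednrb (-0.41 ± 0.48) lay below 0 without passing the test.

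A further comparison asked whether known target genes of a signal were higher near the bins that hold it. Bins within 3 bins of a source were compared with bins at least 12 bins (192 µm) away, drawn from the same regions in the same numbers. The matching was done within each embryo, and the embryos drew on different regions. Near Shh, most bins came from regions 15, 14 and 18 in replicate 1 and from regions 9, 26 and 14 in replicate 2. The folds of the 2 embryos can therefore come from different tissues. Several targets of Wnt and fibroblast growth factor (FGF) signalling were higher near their sources, while of 8 hedgehog targets 1 was higher and 1 lower near Shh. Over 7 sources, 12 of 58 tested targets were higher and 2 were lower (edgeR, adjusted p under 0.05 over all genes tested for that source), and 27 and 5 at an unadjusted p under 0.05. DESeq2 gave 9 higher and 2 lower.

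Near bins with the Wnt ligands Wnt1, Wnt3, Wnt3a, Wnt7a and Wnt7b, 7 of 10 target genes rose (9 when adjusted over the list alone, 5 with DESeq2). The inhibitor Apcdd1 stood at 239 ± 28.5 CPM near and 87.2 ± 5.49 CPM far (log2 fold 1.46, edgeR adjusted p = 9.7e-05), and the feedback gene Axin2 at 211 ± 35.8 and 85.9 ± 16.7 CPM (1.29, adjusted p = 0.00321). Notum rose by a log2 fold of 2.01, the stem cell gene Lgr5 by 1.68, the transcription factors Lef1 and Tcf7 by 1.60 and 1.55, and Nkd1 by 0.81. The ubiquitin ligase genes Znrf3 (0.40) and Rnf43 (0.34) did not pass. The list's median log2 fold was 1.51 (1.60 and 1.00 in replicates 1 and 2), above all of 10000 random lists of matched expression. These lists were matched on mean expression alone, not on how strongly a gene varies between places. Some lists of other signals also lay far from 0. Near Shh, the Vegfa list had a median of 0.74 and the Aldh1a2 list of -0.84. Ranks among random lists, here and below, therefore do not by themselves show an effect of the signal. Outside the list, Sp7 (2.29), Wnt2 (2.23), Krt14 (2.18) and Tbx4 (1.92) were higher and Rbp4 (-1.98) lower.

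Near Fgf8, 4 of 10 targets rose (6 when adjusted over the list alone, 2 with DESeq2). They were the pathway inhibitors Spry4 (log2 fold 1.68, edgeR adjusted p = 0.00203), Dusp6 (1.43) and Spry1 (1.08) and the transcription factor Etv4 (1.40). Spry4 stood at 105 ± 4.27 CPM near and 32.2 ± 0.401 CPM far. Spred1 (0.26) and Etv5 (0.42) did not pass. The median log2 fold was 0.81 (0.72 and 0.88), again above all random lists. Krt17 (2.84), Tfap2b (1.82) and Shox2 (1.67) were higher near Fgf8 outside the list, and Cxcl14 (-2.60) and Col1a1 (-1.78) lower. Matching on region thus left near and far bins that differed in these genes, and finer differences in tissue stay open. Bins near Fgf8 were deeper than bins far from it, with medians of 1891 and 1307 UMIs in replicate 1. Near bins were deeper for the other sources as well, apart from Shh in replicate 1 (1353 near and 1375.5 far).

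Near Shh, the hedgehog antagonist Hhip rose (44.9 ± 12.98 CPM near and 10.9 ± 3.54 CPM far, log2 fold 2.05, edgeR adjusted p = 0.043). Nkx6-1, a ventral neural tube factor, fell (2.75 ± 3.89 and 40.5 ± 44.6 CPM, adjusted p = 0.0477), with 0 CPM near Shh in replicate 1. Adjusted over the list alone, 6 targets were higher and 1 was lower, and DESeq2 gave 2 and 1. With bins also matched on depth, edgeR gave 0 higher and 0 lower (6 and 1 at an unadjusted p under 0.05). Ptch1 had a log2 fold of 1.60 (adjusted p = 0.051) and Foxf1 of 2.22 (adjusted p = 0.173). The median log2 fold over the 8 targets was 1.82 (1.16 and 1.996), above all random lists. Outside the list, Nkx2-1 was higher (5.45), as was Thbs1 (1.84), and Calb1 (-2.53), Gas1 (-2.27) and Cdon (-1.57) were lower.

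The other 4 sources gave fewer calls. The source itself differed less between near and far bins there than for Shh (log2 fold 4.79) and Fgf8 (4.60). Its log2 fold was 2.74 for Aldh1a2, 1.52 for Bmp4, 1.33 for Dll1 and 0.68 for Vegfa, so their comparisons may show less. The Wnt ligands Wnt3, Wnt7a and Wnt7b had 2.15, 1.19 and 2.85, and their list gave the most calls. Summed, as the source was defined, the Wnt ligands stood at 38.5 CPM near and 8.50 CPM far in replicate 1. In replicate 2 they stood at 38.8 and 5.15 CPM. Aldh1a2 had a contrast of similar size (63.1 and 8.56 CPM in replicate 1, 64.7 and 10.6 CPM in replicate 2). A weaker source contrast therefore does not by itself account for the fewer calls near Aldh1a2. For Bmp4, Dll1 and Vegfa it stays open. Near Aldh1a2, which makes retinoic acid, the degrading enzyme gene Cyp26b1 fell (66.3 ± 1.75 CPM near and 112 ± 9.84 CPM far, log2 fold -0.76, edgeR adjusted p = 0.0265), and no target was higher (3 at an unadjusted p under 0.05, 2 adjusted over the list alone, 0 with DESeq2). Crabp2 had a log2 fold of 0.03 and Stra6 of 0.60. No Bmp4 target passed in either direction with edgeR (1 higher and 1 lower at an unadjusted p under 0.05, 1 higher adjusted over the list alone, 0 with DESeq2). Id3 (0.07) and Id2 (-0.13), the classical targets of bone morphogenetic proteins, were close to 0. No Dll1 target passed with edgeR (2 higher and 1 lower at an unadjusted p under 0.05, 1 and 1 adjusted over the list alone, 0 with DESeq2), with Hes1 at 0.36 and Heyl at 0.19. No Vegfa target passed with edgeR (1 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone, 0 with DESeq2). The endothelial genes Kdr (-0.87) and Pecam1 (-0.20) had negative log2 folds. The median log2 fold for Aldh1a2 was 0.68 in the fit over both embryos but 0.21 and 0.22 in replicates 1 and 2 alone. It was 0.01 for Bmp4 (0.14 and -0.07), 0.22 for Dll1 (0.32 and 0.05) and -0.38 for Vegfa (-0.18 and -0.49). The fitted medians for Aldh1a2, Bmp4, Dll1 and Vegfa lay at the 100, 46.8, 99.91 and 0.38 percentile of random lists. For Vegfa the median was -0.08 when bins were also matched on depth and 0.03 when matched on the authors' clusters, and the Dll1 list had a higher median near Fgf8 (0.28) than near Dll1.

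Other genes changed near these sources. Near Aldh1a2, the mesothelial gene Upk3b was higher (1.83), and Nppa (-2.62), Cxcl14 (-2.22), Krt5 (-2.05) and Prdm1 (-1.98) were lower. Near Bmp4, Barx1 was higher (1.79), and Nppa (-1.92), Hbb-bt (-1.61), Hbb-bs (-1.46) and Wt1 (-1.42) were lower. Near Dll1, the neuronal factor Neurod6 was higher (1.40), and Nkx2-1 (-3.22), Tbx5 (-2.52), Thbs1 (-1.49) and Irx2 (-1.31) were lower. Near Vegfa, Nr2f1 (1.47) alone passed among 12153 genes tested. Without the embryo as a block no target passed for any source with edgeR, in either direction, with 17 higher and 2 lower at an unadjusted p under 0.05. Without matching on region, 21 targets were higher and 4 lower with edgeR. Of 11 Bmp4 targets 7 were then higher and 1 lower, and of 6 Dll1 targets 4 were higher and 1 lower.

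**Figure D2:**
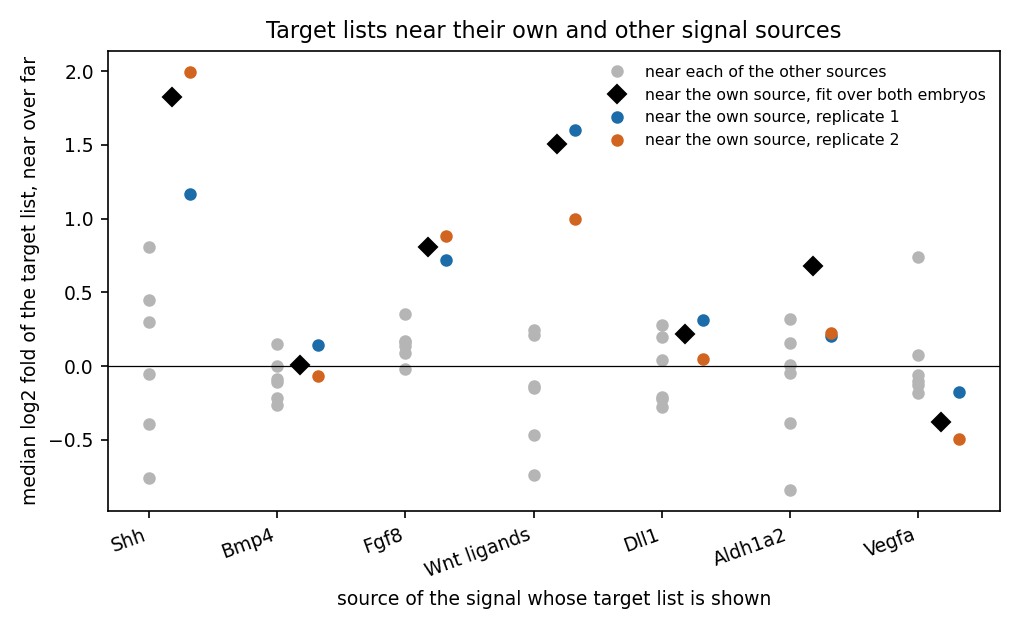
Median log2 fold, near over far, of each of the 7 target lists (horizontal axis), near its own source as fitted over both embryos (black) and in each embryo (blue and orange), and near each of the other sources (grey). The Shh, Wnt and Fgf8 lists stand at 1.82, 1.51 and 0.81 near their own source, above every other source.

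The 2 embryos were compared as single libraries, with no test. Their CPM values correlated closely across 10899 genes (Pearson's r of log2 CPM 0.965). Of 11565 genes with at least 1000 UMIs in the embryo where they were higher, 322 (2.78%) differed at least 2-fold, 194 of them higher in replicate 2 and 128 in replicate 1. With a minimum of 300 UMIs these were 267 and 266, and by the mean of the ratios within regions 66 and 23. The Y-linked genes separated the embryos fully. Kdm5d, Ddx3y, Eif2s3y and Uty had 14924, 13928, 10218 and 9055 UMIs in replicate 2 and 0 in replicate 1. They were at least 3771-fold, 3519-fold, 2582-fold and 2288-fold higher, against a floor of 3 counts in the whole library. Xist was not measured.

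Among the other largest ratios, the hormone gene Gcg had 1217 UMIs in replicate 2 and 3 in replicate 1 (307-fold, 95% counting interval 105 to 1493). The cortical factors Eomes (24.5-fold) and Emx1 (13.8-fold), the testis gene Amh (5.64-fold) and Hoxb8 (5.61-fold) were also higher in replicate 2, as was Capn11 (115-fold, interval 58.1 to 267). Higher in replicate 1 were the posterior Hox genes Hoxc12 (1160 UMIs against 1, 1530-fold, interval 274 to 60500), Hoxd12 (20.6-fold) and Hoxd11 (12.6-fold). The forebrain factors Otp (158-fold), Vax1 (28.8-fold), Nkx2-1 (8.40-fold), Otx2 (7.27-fold) and Fezf1 (7.16-fold) were higher there too. So were the epithelial genes Krt6a (24.5-fold) and S100a14 (8.48-fold). The intervals cover counting error only. All of these are ratios of whole libraries. The mean log2 difference over regions, replicate 2 minus replicate 1, was 0.28 for Eomes, 0.15 for Emx1, 3.24 for Capn11 and -2.24 for Hoxd11. This mean counts each region alike, so a gene confined to a few regions has a small mean by construction. For Gcg, at 307-fold, it was 0.74. Small means therefore do not show that the embryos were alike within the regions that express a gene. The same limit holds for the counts by the mean of the ratios within regions.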

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

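Matching on region and bin depth, and leaving out touching bins around a source, were chosen after seeing the data, and all other alternatives were fixed earlier. Of the alternative values, 45 were counts that moved by over 1.5 times or medians that moved by more than the SD between embryos, 2 no longer passed the test and 6 changed sign. The excess of known partners was judged by its direction and its test alone. Genes higher in a region stayed within 1.5 times the main count of 367 in all 7 alternatives, with 366 without the embryo as a block. Leaving out each embryo gave 0.17 to 0.18 for known minus re-paired partners. For regions, single pairs and single targets it leaves no residual degrees of freedom, so it gave folds but no counts. Where no cause is given below, the cause was not tested.

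The excess of known over re-paired partners was 0.0107 (permutation p = 0.36) with the expected value taken within regions and 0.00939 (p = 0.377) within the authors' clusters. By construction, these take out what partners share by region. It passed but was lower with 2000 UMIs per gene (0.0774) and at up to 12 bins (0.102). Pairs above expectation numbered 13 in the same bin, 16 at 2 to 3 bins, 15 with 500 UMIs per bin, 0 at up to 12 bins, 0 within regions and 0 within the authors' clusters. Pairs below numbered 11 in the same bin and 0, 0 and 0 in the last 3 of these. The last 3 gave 17, 11 and 13 pairs above and 7, 15 and 12 below at an unadjusted p under 0.05 with limma, and no other tool was run.

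Targets higher near a source numbered 7 with at least 5 source UMIs, 7 with source bins counted as near, 21 without matching on region and 0 without the embryo as a block. Those lower numbered 0 with at least 5 source UMIs, 1 with near bins at most 1 bin away, 0 with matching on the authors' clusters, 4 without matching on region, 0 without the block, 1 with matching on depth and 1 without touching bins. At an unadjusted p under 0.05, edgeR gave 4 lower with at least 5 source UMIs, 4 with the authors' clusters, and 17 higher and 2 lower without the block. DESeq2 was run only in the main setting (9 higher and 2 lower). The embryos differ in level, and without the block this difference enters the spread. Fgf8 could not be tested with at least 5 source UMIs or with near bins at most 1 bin away, since replicate 2 then had 177 and 136 near bins, under the minimum of 200.

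The Bmp4 median of 0.01 changed sign to -0.0296 with near bins at most 1 bin away, -0.0857 with the authors' clusters, -0.0296 with matching on depth and -0.0751 without touching bins. Leaving out each embryo gave -0.0683 (without replicate 1) to 0.144 (without replicate 2). Without matching on region the Bmp4 median was 1.18. The Vegfa median of -0.38 became 0.0329 with the authors' clusters, -0.0200 with at least 5 source UMIs and -0.0781 with matching on depth. The medians near Shh, Fgf8, Wnt ligands, Dll1 and Aldh1a2 kept their sign in every alternative run, and that near Aldh1a2 moved by more than the spread between embryos in 10 of 12, to 0.206 and 0.223 with an embryo left out. Without replicate 1 the Dll1 median was 0.0458, and without replicate 2 the Vegfa median was -0.178. Genes at least 2-fold apart between embryos numbered 322, 331 when scaled by the median of gene ratios, 533 with 300 UMIs and 89 by the mean of the ratios within regions. At the depth near Shh, 36% of simulated 1.5-fold rises and 14% of falls to 0.667-fold were recovered, so many changes of this size would be missed.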

Other observations

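The settings with expected values within regions and with 500 UMIs per bin were fixed before the patterns were seen, but were chosen as tests of an explanation after their results were seen. The tests of depth for the hedgehog co-receptors and of touching bins for the target lists were chosen after the patterns but before their own results were seen, and all other tests of explanations after the result was seen. The series has a single group, so no biological explanation was tested.

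Pairs that need cell contact, such as Notch, ephrin and adhesion partners, had a higher median co-occurrence in neighbouring bins than pairs with a secreted ligand, in both embryos. In replicate 1 the median log2 ratio of the 24 contact pairs was 0.38 for bins up to 24 µm apart and 0.24 for bins 400 to 800 µm apart. In replicate 2 it was 0.05 and 0.07. The 77 secreted pairs stood at 0.06 and 0.08 in replicate 1 and at -0.15 and 0.10 in replicate 2. The difference between the kinds of pairs was not tested.

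Of genes with at least 1000 UMIs in the higher embryo, 7 were at least 2-fold apart in all 31 regions, all higher in replicate 2. They were the 4 Y-linked genes, Capn11, Cdc42 and Actr2, the last 2 named after their values were seen. Cdc42 and Actr2, which control the actin skeleton in most cells, were 3.55-fold and 3.36-fold higher, with 8099 against 1730 and 4804 against 1083 UMIs. Capn11 had 1212 against 8 UMIs.

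The hedgehog co-receptor genes Gas1, Boc and Cdon lay apart from Shh, while the receptor gene Ptch1 lay close to it. If the regions that hold Shh merely held few co-receptor UMIs, bins near and far from Shh within the same regions would be alike, but the median log2 fold of the 3 genes, that of Cdon, was -1.57 (-1.67 and -1.42 in replicates 1 and 2), and -1.52 (-1.63 and -1.36) with depth also matched. For Gas1 and Cdon, this argues against depth and against the regions as clustered here. Finer differences in tissue within a region stay open, since Nkx2-1 also differed strongly between these bins (log2 fold 5.45). For Boc, region and depth both stay open, since its log2 fold of -0.79 (-0.46 in replicate 2) did not pass (edgeR adjusted p = 0.338, and 0.526 with depth matched). With depth matched, Gas1 missed the threshold (edgeR adjusted p = 0.0211 before and 0.0598 after) with a log2 fold of -2.27 before and -2.15 after, each with a standard error of 0.20, on fewer bins.

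Known partners co-occurred more than re-paired ones. An excess that comes from sharing a region would vanish when the expected value is taken within regions, and it was then 0.0107, within 2 SD of the re-paired medians (0.0234). Shallow bins do not account for it, since bins with at least 500 UMIs gave 0.171, above 2 SD (0.0819). The excess may therefore lie mostly between regions, and finer co-occurrence within them was not detectable over the list as a whole.

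The median log2 folds of the Shh, Fgf8 and Wnt target lists were above 0 near their sources, although near Shh 1 target passed higher and 1 lower. If lists were higher near any source, another source would give as high a median, but the own source exceeded the highest other one by 1.02 for Shh (Vegfa) and 1.26 for Wnt ligands (Shh), in both embryos by more than the SD between embryos. For Fgf8 the margin was 0.46 (Vegfa), but in replicate 1 it was 0.00187, so the possibilities cannot be told apart. Matching on depth left at least 0.800 of each fitted median, and leaving out touching bins at least 0.688. For the fitted medians, this argues against depth and against spread of RNA into touching bins as the whole cause. With depth matched, however, the Wnt median in replicate 2 fell from 0.995 to 0.546. No Shh target then passed in either direction with edgeR (6 higher and 1 lower at an unadjusted p under 0.05). Finer differences in tissue within a region stay open for all 3 lists. Near and far bins differed in Krt17 (log2 fold 2.84) and Col1a1 (-1.78) for Fgf8, Krt14 (2.18) for Wnt ligands and Nkx2-1 (5.45) for Shh.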
